A study of Homo sapiens with 102 samples.

How the data were processed

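Small RNA was sequenced from 102 colon tissue libraries of patients with ulcerative colitis (UC), a form of inflammatory bowel disease, and of control patients without inflammatory bowel disease (NIBD). Per the labels' protocols, RNA came from formalin-fixed, paraffin-embedded tissue with a Roche miRNA isolation kit, and libraries were made with an Illumina TruSeq small RNA kit. Per the submitters' processing notes, cutadapt and Bowtie were used with the hg19 build, with no versions given there. Other steps of the counting are not given in the sources used here.

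The authors deposited a table of estimated counts per miRNA row and a table of normalized values. In the deposited estimated counts, 53.4% of the values above 0 were exactly whole numbers, with no tolerance, and the smallest value above 0 was 10, so a 0 means a value under that minimum and not the absence of the miRNA. The deposited normalized signal equalled the rounded estimated count divided by 1 factor per library, from 0.252 to 1.723. These factors equalled DESeq2's size factors over the 102 libraries within a relative difference of 2.2e-16. The table of estimated counts also held 52 columns that match no sample described here, which were not used.

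The table held 2162 rows. Of these, 874 were reference miRNA rows and 1288 were offset rows, which count reads that start a few bases before or after the reference start and held 5.7% of all counts. Rows for locus copies of 1 mature miRNA, such as miR-26a-1-5p and miR-26a-2-5p, or miR-199a-3p and miR-199b-3p, share reads, so their values are uncertain and not independent. Names are written as miR-31-5p for the row hsa-mir-31-5p. Some rows give no arm, such as miR-375, miR-429 and miR-215, and are named as the file gives them. No genome coordinates are given, because the annotation at hand was of another build than hg19.

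Groups came from the labels: 43 libraries of inflamed UC tissue, 43 of non-inflamed UC tissue and 16 of NIBD tissue. The labels name no patients, so samples of 1 patient could not be paired and may be counted as separate samples. The p-values therefore measure only the spread between these samples. No pair of libraries was a duplicate: over 1926 pairs within groups, the smallest chi-square per degree of freedom was 169.3. The library names and index numbers in the sample descriptions restart in series, which were taken as 4 index series of 28, 36, 30 and 8 libraries. NIBD libraries lay in index series 1 (4), 2 (7) and 3 (5), and index series 4 held UC libraries alone.

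Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit and F test). All 3 groups were fitted together with index series as a covariate. The filter (minimum count 10, minimum total 15) kept 1320 rows, of which 619 were reference and 701 offset rows, and these held 99.995% of the counts. TMM factors ran from 0.665 to 1.371. A row was called at a Benjamini-Hochberg adjusted p under 0.05 over all 1320 rows. The contrasts were both UC groups, weighted equally, against NIBD, each UC group against NIBD, and inflamed against non-inflamed UC. All tests were two-sided. Log2 fold changes are given with their standard errors (SE), and CPM values use TMM-scaled library totals. Plotted log2 CPM used a prior count of 2.

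The miRNA lists, the tests, the alternatives and the rule for named miRNAs were fixed before the data were examined. The 15 lists held epithelial, smooth muscle, fibroblast, endothelial, myeloid, lymphoid, erythrocyte, enteric neuron, inflammation-induced, HOX cluster, let-7, miR-17 family cluster, DLK1-DIO3 cluster, hypoxia and liver miRNAs. No member of the hypoxia and liver lists was among the tested rows matched by arm, so these lists have no value. The other 13 lists were tested with camera at a preset correlation of 0.01, adjusted over 13 lists and 4 comparisons, and with fry. Of locus copies, the row with the highest mean count stood for the miRNA. miR-155-5p is in the lymphoid and the inflammation-induced list, and miR-223-3p in the myeloid and the inflammation-induced list. Members of a list are not independent. The myeloid list holds both arms of miR-142, miR-223 and miR-424, and the endothelial list both arms of miR-126. The erythrocyte list holds both arms of miR-144 and of miR-486. Counts of members are therefore not counts of independent changes.

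Per comparison, the named miRNAs were the 8 largest rises and 8 largest falls among called rows with an average log2 CPM of at least 5, and the 4 smallest p-values in each direction. Offset rows were named only where the reference row was not called. Added to these were up to 4 called members of each list by p-value, 14 miRNAs fixed for every comparison, and the 5 rows with the highest mean CPM. The alternatives were DESeq2's size factors or library totals in place of TMM, no filter or a mean CPM of at least 10, and DESeq2 1.42.0 or limma-voom (limma 3.58.1) as the test. Others were no covariate, only the groups compared, the replicate number as a block, the authors' normalized table with limma on log2 of the value plus 1, offset rows summed into reference rows, and each index series alone. Lists were also tested with an estimated correlation, with fry and without the covariate.

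Each step was tested on simulated data with 200 of 1320 rows changed. For inflamed UC against NIBD, 69% of rows changed by 1 on the log2 scale were called and 46% of those changed by 0.5. Among the 525 rows with a mean CPM of at least 10, these shares were 92.1% and 61.9%. Of the 134 simulated calls, 19 were unchanged rows, more than the threshold allows, and 13 of these 19 had a dispersion over 5, as 192 rows do. For non-inflamed UC against NIBD, 61% and 31% were called, with 18 unchanged rows among 110 calls, 4 of them at a mean CPM of at least 10. For inflamed against non-inflamed UC, 77% and 53% were called, with 11 unchanged rows among 141 calls. For UC against NIBD, 68% and 36% were called, with 15 unchanged rows among 119 calls. Calls of sparse rows are therefore less certain than the threshold says, and each count was also taken without the 192 rows of dispersion over 5.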

Results

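MicroRNAs, short RNAs that lower the output of their target mRNAs, were counted in 43 inflamed UC, 43 non-inflamed UC and 16 NIBD colon tissue libraries. Totals, in megacounts (M), ran from 3.69 to 18.86 M (median 10.42 M) in inflamed UC, from 7.32 to 17.66 M (12.04 M) in non-inflamed UC and from 2.70 to 16.66 M (10.93 M) in NIBD. miR-21-5p, widely expressed and known to rise in inflamed tissue, took 16.2% of all counts. miR-192-5p, an intestinal epithelial miRNA, took 8.1%, and miR-143-3p, abundant in smooth muscle and other mesenchymal cells, took 7.9%. The 2 rows of miR-26a-5p took 3.7% each and share reads.

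Many but not all inflamed UC libraries lay apart from the other libraries along the first principal component of log2 CPM, which held 15.0% of the variance. Group accounted for a share of 0.48 of the variance of that component (R squared, permutation p = 1e-05, the smallest that 100000 resamples can give), and index series for 0.02 (permutation p = 0.632). The second component held 11.8% of the variance and followed the index series, with an R squared of 0.64 (permutation p = 1e-05) against 0.02 for group (permutation p = 0.423). Index series was therefore kept as a covariate in each comparison.

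**Figure D1:**
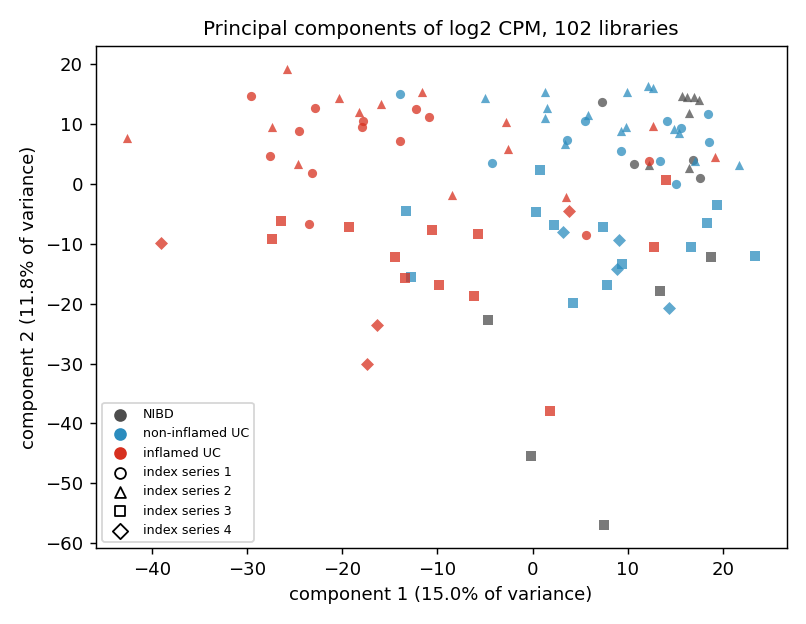
Each point is 1 of 102 libraries on principal components 1 (horizontal) and 2 (vertical) of log2 CPM, in units of component score, with color for group and shape for index series. Component 1 (15.0% of variance) parts many inflamed UC libraries from the rest, and component 2 (11.8%) follows the index series.

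The first question was how UC tissue of either state differs from NIBD tissue. miR-31-5p, an epithelial miRNA known to be induced by inflammatory signals, showed the largest rise among called rows with an average log2 CPM of at least 5. Its log2 fold change was 3.81 ± 0.66 (SE, 86 UC against 16 NIBD libraries), 2.98 in limma-voom and 3.01 with the authors' table. With the replicate number as a block it was 2.25 and did not pass (edgeR adjusted p = 0.273). That number does not pair the samples, and with it the contrasts with NIBD rest mainly on UC libraries that share numbers with NIBD libraries. miR-223-3p, a miRNA of neutrophils and monocytes, rose by 1.48 ± 0.28, and miR-424-3p and miR-424-5p rose by 1.05 ± 0.16 and 1.09 ± 0.19. On the other side, miR-375, expressed in enteroendocrine and goblet cells, fell by 1.15 ± 0.24 on the log2 scale, and miR-192-5p fell by 0.99 ± 0.25. miR-31-5p lay above the NIBD median in 77 of 86 UC libraries and miR-424-3p in 84 of 86.

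In edgeR's quasi-likelihood test, 205 of 1320 rows were called between UC and NIBD, 118 higher and 87 lower in UC. Of these, 65 of the higher and 51 of the lower rows were reference rows, and the rest were offset rows. The adjusted p was 1.63e-05 for miR-31-5p, 1.75e-06 for miR-424-3p, 8.46e-05 for miR-223-3p, 0.000373 for miR-375 and 0.00336 for miR-192-5p. All 6 tested members of the myeloid list rose, 6 also when adjusted over the list alone (camera adjusted p = 3.18e-06; adjusted p = 0.0814 with an estimated correlation). Of 11 tested epithelial miRNAs, 6 fell and 5 did not pass, and 8 fell when adjusted over the list alone (camera adjusted p = 5.85e-05; adjusted p = 0.319 with an estimated correlation). Of the 6, the miR-200b-3p call (adjusted p = 0.045) was lost in 12 of 16 fits that each left out 1 NIBD library, and with library totals. Of 13 inflammation-induced miRNAs, 8 rose, 8 also when adjusted over the list alone (camera adjusted p = 7.68e-05; adjusted p = 0.291 with an estimated correlation). These included miR-21-5p (0.67 ± 0.15), miR-146b-5p (0.82 ± 0.19) and miR-212-3p (0.87 ± 0.17), while miR-146a-5p (0.28 ± 0.19) and miR-155-5p (0.37 ± 0.21) did not pass. Of 22 DLK1-DIO3 cluster miRNAs, a large cluster expressed from the maternal chromosome 14, 4 rose, 4 also when adjusted over the list alone (camera adjusted p = 0.00249; adjusted p = 0.456 with an estimated correlation), led by miR-431-5p at 1.17 ± 0.25. Other named rises were those of miR-708-5p (0.99 ± 0.22), miR-223-5p (1.24 ± 0.27), miR-142-5p (0.76 ± 0.21), let-7i-5p (0.42 ± 0.14) and miR-145-3p (0.52 ± 0.16). Other named falls were those of miR-592 (-1.02 ± 0.28), miR-190a (-0.88 ± 0.22), miR-194-2-3p (-0.83 ± 0.25), miR-196a-2-5p (-0.76 ± 0.22), miR-532-5p (-0.55 ± 0.13), miR-30e-3p (-0.39 ± 0.10) and miR-107 (-0.35 ± 0.09). The named falls also held offset rows, those of miR-203 (-0.76 ± 0.23) and miR-215 (-0.90 ± 0.24), while the reference row of miR-215 stood at -0.07 ± 0.29. Of 7 HOX cluster miRNAs, 2 fell, 2 also when adjusted over the list alone, miR-196a-2-5p and miR-10a-5p (camera adjusted p = 0.0467; adjusted p = 0.456 with an estimated correlation). The miR-10a-5p call (-0.38 ± 0.14) was lost in 11 of 16 fits that each left out 1 NIBD library, with an adjusted p of up to 0.12. It was also lost with library totals, without the covariate, with the replicate number as a block, with offset rows summed and without index series 4. Of 4 enteric neuron miRNAs, miR-9-2-5p fell, and 2 fell when adjusted over the list alone (camera adjusted p = 0.046; adjusted p = 0.276 with an estimated correlation). The other lists did not pass in camera: 1 member rose each of the smooth muscle (miR-145-3p; adjusted p = 0.98), endothelial (miR-126-5p; 0.116), lymphoid (miR-342-3p; 0.119) and let-7 lists (let-7i-5p; 0.814), and none of the fibroblast (0.0825), erythrocyte (0.134) and miR-17 family lists (0.272). Of these calls, that of miR-342-3p was lost in 6 of 16 leave-out fits, that of miR-145-3p with offset rows summed and that of miR-126-5p without the covariate. With library totals in place of TMM, 69.2% of the calls were higher in UC, against 57.6%, while with limma-voom 43.8% were. Within index series 1, 2 and 3 alone, 5, 27 and 13 rows were called, and 201 of the 205 calls had the same sign in all 3. The calls were made on these same libraries. Here and in the comparisons below, such agreement of sign is therefore partly built in and is not a replication.

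The second question was how inflamed UC tissue differs from NIBD tissue. Of the epithelial list, 8 of 11 miRNAs fell, and all 6 myeloid and 5 erythrocyte miRNAs rose in inflamed UC (adjusted p of 0.276, 0.103 and 0.371 for the lists with an estimated correlation). The members of each list moved together, with estimated correlations of 0.60, 0.43 and 0.76 in this order, so these counts are not of independent changes. miR-375 fell by 1.68 ± 0.27 on the log2 scale and miR-192-5p fell by 1.58 ± 0.27, with 40 and 39 of 43 inflamed libraries below the NIBD median. Without inflamed UC replicates 3 and 18, which had the lowest miR-375, they stood at -1.60 and -1.50 and both passed. miR-223-3p rose by 1.94 ± 0.30, with 42 of 43 above it, and miR-31-5p rose by 4.26 ± 0.69, a fold of 19.22, with 40 of 43 above it. The mean CPM of miR-31-5p was 31.9 ± 40.4 (SD, n = 16) in NIBD and 613.6 ± 536.4 (SD, n = 43) in inflamed UC. With the replicate number as a block, which does not pair the samples and leaves fewer UC libraries for this contrast, its log2 fold change was 3.06. It did not pass there (edgeR adjusted p = 0.074).

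**Figure D2:**
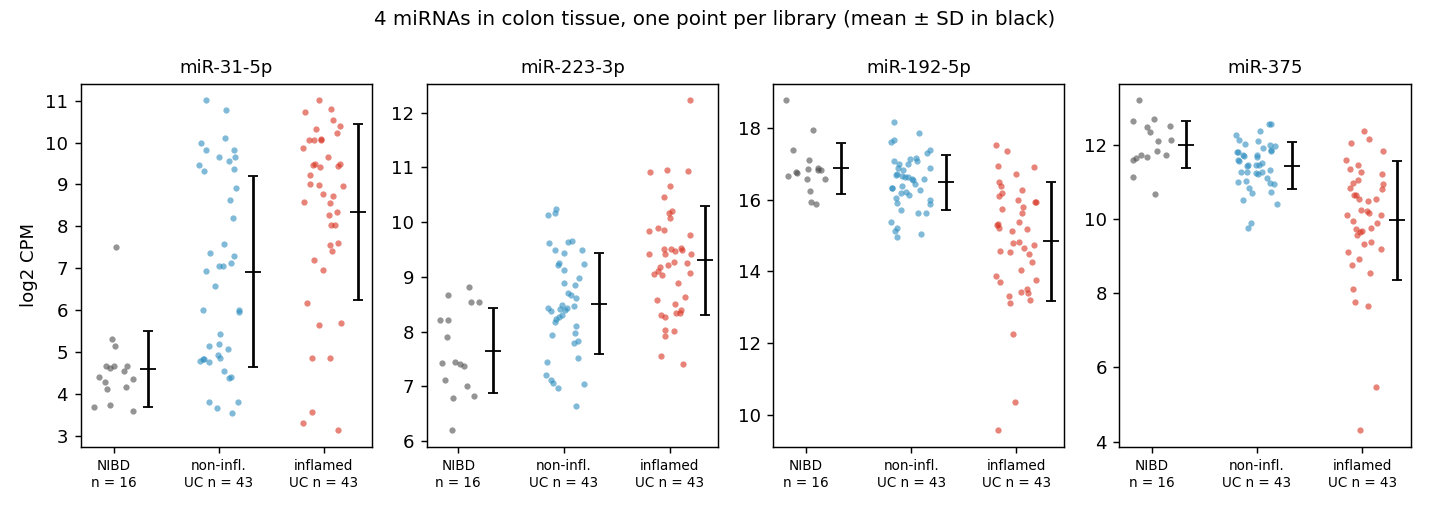
Log2 CPM of miR-31-5p, miR-223-3p, miR-192-5p and miR-375 in each library by group, with the group mean and SD as a black bar. miR-31-5p had a mean of 4.59 in NIBD, 6.91 in non-inflamed UC and 8.34 in inflamed UC, with an SD of 0.91 in NIBD against 2.28 and 2.10 in the UC groups.

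In edgeR's quasi-likelihood test, 439 of 1320 rows were called between inflamed UC and NIBD, 231 higher and 208 lower. Reference rows made up 125 of the higher and 109 of the lower calls. The adjusted p was 1.17e-06 for miR-375, 4.08e-06 for miR-192-5p, 9.79e-07 for miR-223-3p and 1.71e-06 for miR-31-5p. Of 11 epithelial miRNAs, 8 fell and none rose, 8 also when adjusted over the list alone (camera adjusted p = 3.18e-06; adjusted p = 0.276 with an estimated correlation). The 8 were miR-375, miR-192-5p, miR-194-2-5p and the miR-200 family members miR-141-3p, miR-200a-3p, miR-200b-3p, miR-200c-3p and miR-429, with miR-200b-3p at -1.17 ± 0.24 and miR-200c-3p at -1.27 ± 0.25. miR-182-5p (-0.17 ± 0.14), miR-183-5p (-0.09 ± 0.14) and miR-96-5p (0.10 ± 0.41), which are transcribed together, did not pass. miR-190a fell by 1.49 ± 0.24 and miR-194-2-3p fell by 1.49 ± 0.26, followed by the offset row of miR-215 (-1.45 ± 0.26), miR-192-3p (-1.37 ± 0.28) and miR-592 (-1.34 ± 0.31). The reference row of miR-215 stood at -0.41 and did not pass (edgeR adjusted p = 0.314).

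All 6 myeloid miRNAs rose, 6 also when adjusted over the list alone (camera adjusted p = 2.46e-05; adjusted p = 0.103 with an estimated correlation). Among them, miR-424-3p (1.20 ± 0.17) and miR-424-5p (1.16 ± 0.20) act in monocyte differentiation but are also made by other cells. All 5 erythrocyte miRNAs rose, 5 also when adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.371 with an estimated correlation). Among these, miR-451a rose by 1.02 ± 0.29 and miR-486-5p by 1.25 ± 0.30. Of 8 lymphoid miRNAs, 5 rose, and 6 when adjusted over the list alone (camera adjusted p = 0.0461; adjusted p = 0.425 with an estimated correlation), with miR-150-5p at 0.87 ± 0.26 and miR-155-5p at 0.73 ± 0.23, the latter call lost in limma-voom and with the authors' table. Both endothelial miRNAs rose, miR-126-3p by 0.65 ± 0.19 and miR-126-5p by 0.55 ± 0.13, while their list did not pass (camera adjusted p = 0.0825). Of 6 fibroblast miRNAs, 4 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.0611), with miR-199a-2-3p and miR-199b-3p, which share reads, at 0.37 ± 0.10 and 0.38 ± 0.10. Smooth muscle miRNAs stayed mostly within their errors, with miR-143-3p at 0.10 ± 0.22 and miR-145-5p at -0.13 ± 0.21. Of 5, 1 rose, miR-145-3p at 0.69 ± 0.17 (camera adjusted p = 0.86 for the list). The miR-145-3p call was lost with offset rows summed and with the replicate number as a block, with values down to 0.32 over the alternatives.

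Of 13 inflammation-induced miRNAs, 9 rose, and 10 when adjusted over the list alone (camera adjusted p = 0.000131; adjusted p = 0.293 with an estimated correlation), with miR-21-5p at 0.82 ± 0.16 and miR-212-3p at 1.01 ± 0.18. miR-146a-5p, at 0.40 ± 0.20, did not pass. Of 7 HOX cluster miRNAs, which lie among the genes that set position along the body axis, 5 fell, 5 also when adjusted over the list alone (camera adjusted p = 0.00697; adjusted p = 0.348 with an estimated correlation). The largest of these falls was that of miR-196a-2-5p, at -1.27 ± 0.24, and miR-10a-5p stood at -0.67 ± 0.15. Of 22 DLK1-DIO3 miRNAs, 11 rose and none fell, 11 also when adjusted over the list alone (camera adjusted p = 0.000551; adjusted p = 0.402 with an estimated correlation), with miR-431-5p at 1.68 ± 0.27 and miR-382-5p at 0.72 ± 0.14. Of 7 let-7 miRNAs, let-7i-5p (0.81 ± 0.15) and let-7e-5p (0.36 ± 0.13) rose and let-7f-2-5p (-0.20 ± 0.07) fell, the last not passing with library totals (camera adjusted p = 0.977 for the list). Of 12 miRNAs of the miR-17 family clusters, 5 fell, among them miR-20a-5p (-0.53 ± 0.13) and miR-17-5p (-0.42 ± 0.12), and miR-363-3p rose (0.90 ± 0.32; camera adjusted p = 0.285 for the list). Of 4 enteric neuron miRNAs, 2 fell, miR-9-2-5p (-0.47 ± 0.15) and miR-137 (-0.53 ± 0.22) (camera adjusted p = 0.123). The miR-137 call was lost in 10 of 16 fits that each left out 1 NIBD library, stood at -0.35 without NIBD replicate 15, and was kept in 1 of 15 alternatives. With library totals, 63.5% of the calls were higher in inflamed UC, against 52.6% (45.4% with limma-voom), and the median of all rows was 0.19 against 0.08 with TMM. Within index series 1, 2 and 3 alone, 16, 266 and 7 rows were called, and 413 of the 439 calls had the same sign in all 3.

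**Figure D3:**
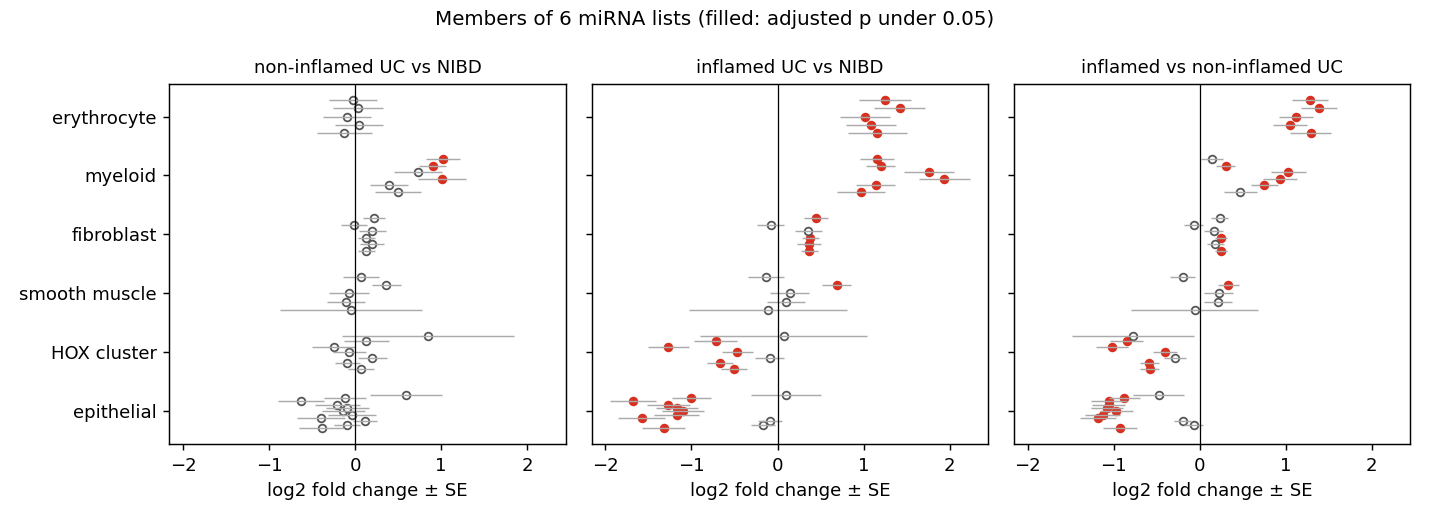
Log2 fold change with SE (horizontal) of each tested member of 6 miRNA lists (vertical) in 3 comparisons, with filled points for members called at an adjusted p under 0.05. In inflamed UC, 8 of 11 epithelial and 5 of 7 HOX cluster miRNAs lie below 0 as filled points and all 5 erythrocyte miRNAs lie above it, while in non-inflamed UC against NIBD the filled points are 3 myeloid miRNAs.

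The third question was whether UC tissue without inflammation differs from NIBD tissue. miR-31-5p was higher by 3.36 ± 0.66 on the log2 scale, with 37 of 43 non-inflamed libraries above the NIBD median. The libraries varied widely, with a mean of 350.4 ± 485.4 CPM (SD, n = 43) and a median of 122.4 CPM. miR-424-5p rose by 1.02 ± 0.20, miR-424-3p by 0.90 ± 0.16 and miR-223-3p by 1.01 ± 0.28. Epithelial miRNAs were not called, with miR-192-5p at -0.40 ± 0.28, miR-200b-3p at -0.09 ± 0.25 and miR-375 at -0.63 ± 0.27. However, miR-375 passed with only the groups compared, and its values ran from -1.32 to -0.57 over the alternatives. It lay below the NIBD median in 34 of 43 non-inflamed libraries, so a fall of miR-375 is not excluded.

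In edgeR's quasi-likelihood test, 38 of 1320 rows were called, 34 higher and 4 lower in non-inflamed UC. Reference rows made up 18 of the higher and all 4 of the lower calls. In limma-voom 14 rows were called, and 23 to 43 in fits that each left out 1 NIBD library. Without the 192 rows of dispersion over 5, 20 rows were called, all of them among the 38. The adjusted p was 0.000485 for miR-31-5p, 0.000468 for miR-424-5p, 0.000182 for miR-424-3p and 0.027 for miR-223-3p. With limma-voom, which averages log values, miR-31-5p stood at 2.24 and did not pass (adjusted p = 0.0688). Within index series 1, 2 and 3 it stood at 3.58, 2.43 and 4.33, against 4.63, 4.09 and 4.76 for inflamed UC. The miR-223-3p call was lost in 5 of 16 fits that each left out 1 NIBD library, with an adjusted p of up to 0.067. It was also lost in limma-voom, without the covariate and with the replicate number as a block. With that block, which does not pair the samples and leaves fewer UC libraries for this contrast, miR-31-5p stood at 1.44 (edgeR adjusted p = 0.842). The miR-424-3p and miR-424-5p calls were lost there too. Of 6 myeloid miRNAs, 3 rose, and 4 when adjusted over the list alone (camera adjusted p = 3.18e-06, and 0.0814 with an estimated correlation). The 3 were miR-223-3p and the 2 arms of miR-424, which other cells also make. miR-142-3p (0.50 ± 0.27), miR-142-5p (0.39 ± 0.22) and miR-223-5p (0.73 ± 0.28) did not pass. Of 13 inflammation-induced miRNAs, 5 rose, and 8 when adjusted over the list alone (camera adjusted p = 0.000415; adjusted p = 0.33 with an estimated correlation). The 5 were miR-31-5p, miR-31-3p, miR-223-3p, miR-212-3p (0.72 ± 0.17) and miR-146b-5p (0.66 ± 0.20). miR-31-3p was above the table's minimum in 1 of 16 NIBD and 15 of 43 non-inflamed libraries, and its value ran from 3.76 to 6.77 over the leave-out fits and from 0.09 to 4.34 over the alternatives. The miR-31-3p and miR-146b-5p calls were each lost in 9 of 16 leave-out fits and both in limma-voom and with the authors' table. miR-21-5p stood at 0.51 ± 0.16 (edgeR adjusted p = 0.0559). It did not pass in 10 of 15 alternatives and passed in the others, among them only the groups compared and offset rows summed. The offset row of miR-21-5p rose by 0.84 ± 0.24, a call lost in 3 of 16 leave-out fits, in limma-voom and with the authors' table. No enteric neuron miRNA of 4 was called over all rows, and 1 fell when adjusted over the list alone (camera adjusted p = 0.00643; adjusted p = 0.103 with an estimated correlation). Erythrocyte miRNAs were not called, with miR-451a at -0.10 ± 0.28 (camera adjusted p = 0.36). Of 22 DLK1-DIO3 miRNAs none was called (camera adjusted p = 0.123), nor of 7 HOX cluster (0.766), 11 epithelial (0.0825), 5 smooth muscle (0.766), 6 fibroblast (0.285), 2 endothelial (0.358), 8 lymphoid (0.814), 7 let-7 (0.371) and 12 miR-17 family miRNAs (0.285).

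The 4 lower rows, of which let-7d-3p alone met the naming rule, were let-7d-3p (-0.57 ± 0.16), miR-204-5p (-0.91 ± 0.20), miR-1468 (-0.65 ± 0.16) and miR-216b (-3.40 ± 0.90), the last 3 named after their values were seen. The let-7d-3p value rested on NIBD replicate 13, without which it was -0.23 (adjusted p = 0.684). Within index series 1, 2 and 3 alone, 1, 0 and 7 rows were called, with 77 rows at an unadjusted p under 0.05 in index series 2, and 36 of the 38 calls had the same sign in all 3.

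Of the 38 rows called in non-inflamed UC, 37 were also called in inflamed UC against NIBD in the same direction and none in the opposite one. Independent lists would share 6.0 higher and 0.6 lower rows. Simulated groups with no change against the same NIBD libraries shared 0.17 rows on average and at most 1 in 30 simulations. The simulations drew each row separately and changed neither UC group, while related rows, such as locus copies, share reads. They therefore cannot show how many correlated rows would be shared through the same NIBD libraries. With the NIBD libraries split into separate sets of 8 for the 2 comparisons, the shared calls fell to a median of 3.5 over 20 splits (from 0 to 13), with a median of 4.5 calls for non-inflamed UC. Over 342 rows with an average log2 CPM of at least 5, which are not independent replicates, the covariance of the fold changes was 0.152 against 0.022 in the simulations, a difference of 0.130. The correlation was 0.78 against 0.75 in the simulations. With the NIBD libraries split, the median covariance was 0.144 and the median correlation 0.69.

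The last question was how inflamed differs from non-inflamed tissue within UC. In inflamed tissue 8 of 11 epithelial and 5 of 7 HOX cluster miRNAs fell, and 5 of 5 erythrocyte, 4 of 6 myeloid and 5 of 8 lymphoid miRNAs rose. With an estimated correlation no list passed (adjusted p of 0.276, 0.291, 0.25, 0.291 and 0.337 in this order). miR-192-5p fell by 1.18 ± 0.21, miR-375 fell by 1.06 ± 0.21 and miR-200b-3p fell by 1.08 ± 0.19 on the log2 scale, each below the non-inflamed median in at least 37 of 43 inflamed libraries. miR-451a rose by 1.12 ± 0.20, miR-223-3p by 0.93 ± 0.20 and let-7i-5p by 0.77 ± 0.11. miR-31-5p stood at 0.90 ± 0.40 and did not pass (adjusted p = 0.0683), although it passed in 8 of 15 alternatives, among them limma-voom (1.47, adjusted p = 0.005), DESeq2 (0.92, adjusted p = 0.0327) and library totals (1.05, adjusted p = 0.0309).

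In edgeR's quasi-likelihood test, 437 of 1320 rows were called, 184 higher and 253 lower in inflamed UC. Reference rows made up 97 of the higher and 124 of the lower calls. The adjusted p was 1.16e-05 for miR-192-5p, 3.3e-05 for miR-375, 1.2e-05 for miR-451a, 9.75e-05 for miR-223-3p and 6.43e-08 for let-7i-5p. Of 11 epithelial miRNAs, 8 fell, 8 also when adjusted over the list alone (camera adjusted p = 3.05e-06; adjusted p = 0.276 with an estimated correlation). All 5 erythrocyte miRNAs rose, 5 also when adjusted over the list alone (camera adjusted p = 5.85e-05; adjusted p = 0.25 with an estimated correlation), with miR-486-3p at 1.39 ± 0.21 and miR-144-3p at 1.29 ± 0.24. Of 6 myeloid miRNAs, 4 rose, and 5 when adjusted over the list alone (camera adjusted p = 0.00373; adjusted p = 0.291 with an estimated correlation). These did not include miR-424-5p, at 0.14 ± 0.13. Of 8 lymphoid miRNAs, 5 rose, 5 also when adjusted over the list alone (camera adjusted p = 0.00891; adjusted p = 0.337 with an estimated correlation), with miR-155-5p at 0.72 ± 0.16 and miR-150-5p at 0.59 ± 0.18. Of 7 HOX cluster miRNAs, 5 fell, and 6 when adjusted over the list alone (camera adjusted p = 0.000761; adjusted p = 0.291 with an estimated correlation), with miR-196a-2-5p at -1.02 ± 0.19 and miR-196b-5p at -0.85 ± 0.19. Of 22 DLK1-DIO3 miRNAs, 10 rose, 10 also when adjusted over the list alone (camera adjusted p = 0.000308; adjusted p = 0.371 with an estimated correlation). Of 13 inflammation-induced miRNAs, 3 rose, miR-21-5p (0.32 ± 0.11), miR-155-5p and miR-223-3p (camera adjusted p = 0.00311; adjusted p = 0.367 with an estimated correlation). The miR-21-5p call was lost in limma-voom, without the covariate and without index series 4. None of the other lists passed in camera. Both endothelial miRNAs, which are both arms of miR-126, rose (camera adjusted p = 0.0825). Of 6 fibroblast miRNAs 2 rose, and 3 when adjusted over the list alone (0.0738). The 2 were miR-199a-2-3p (0.25 ± 0.07) and miR-199b-3p (0.25 ± 0.07), which share reads and are not separate changes. Of 5 smooth muscle miRNAs 1 rose, miR-145-3p (0.696). The miR-145-3p call was lost with offset rows summed and without inflamed UC replicates 3 and 18 (0.20, edgeR adjusted p = 0.145). Of 7 let-7 miRNAs, 2 rose and let-7f-2-5p fell (0.569), a fall lost in 9 of 15 alternatives, with values up to -0.03. Of 12 miR-17 family miRNAs 2 rose and 4 fell (0.457), and of 4 enteric neuron miRNAs miR-7-1-5p fell (0.795). Other named falls were those of miR-190a (-1.23 ± 0.19), miR-194-2-3p (-1.33 ± 0.21), miR-335-3p (-0.84 ± 0.14) and miR-362-5p. Other named rises were those of miR-708-5p (0.80 ± 0.16), miR-455-3p (0.61 ± 0.10) and miR-193b-3p (0.59 ± 0.10). With library totals, 60.4% of the calls were higher in inflamed tissue, against 42.1% (36.0% with limma-voom), and the median of all rows was 0.08 against -0.03 with TMM. Within index series 1, 2 and 3 alone, 35, 76 and 0 rows were called, with 175 rows at an unadjusted p under 0.05 in index series 3, and 426 of the 437 calls had the same sign in all 3.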

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

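The runs without libraries under 5 megacounts, without index series 4, without each NIBD library, without inflamed UC replicates 3 and 18 and without rows of dispersion over 5, and the list test with armless rows, were chosen after seeing the data. With no filter, 374 rows were called for UC against NIBD (205 in the report), 154 for non-inflamed UC against NIBD (38) and 843 for inflamed against non-inflamed UC (437), with sparse rows added. With a mean CPM of at least 10, 289 rows were called for inflamed UC against NIBD (439) and 22 for non-inflamed UC, with fewer rows tested. With offset rows summed, 123 rows were called for UC against NIBD, 244 for inflamed UC against NIBD and 232 for inflamed against non-inflamed UC, from 651 rows tested. limma-voom called 14 rows for non-inflamed UC against NIBD, and the cause was not tested. Without rows of dispersion over 5, 20 were called there, 205 for UC against NIBD, 429 for inflamed UC and 420 between the UC states. Leaving out each NIBD library gave 23 to 43 calls for non-inflamed UC, the lowest without NIBD replicate 15 (23), 16 (24), 4 (25) and 6 (25), 166 to 205 for UC and 401 to 451 for inflamed UC. All other alternatives on the 4 counts, those of single index series and of the block aside, stayed within 1.5 times. Without inflamed UC replicates 3 and 18 the counts were 234, 440, 48 and 425, in the order of UC, inflamed UC and non-inflamed UC against NIBD and the UC states. The run with at least 500000 counts removed no library and gives no value.

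Index series alone hold fewer samples. UC against NIBD gave 5, 27 and 13 calls in index series 1, 2 and 3, inflamed UC against NIBD 16, 266 and 7, non-inflamed UC against NIBD 1, 0 and 7, and inflamed against non-inflamed UC 35, 76 and 0. Index series 4 held no NIBD library and 4 of each UC state. In index series 3 alone, miR-17-5p (0.04) and miR-19b-2-3p (0.01) changed sign for inflamed UC against NIBD, and in index series 1 alone let-7d-3p (0.14) did for non-inflamed UC; the cause was not tested.

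The replicate numbers do not pair the samples: same-numbered inflamed and non-inflamed UC libraries had a mean correlation of -0.023, with 8 of 43 pairs over 0.1 and 3 of 43 libraries correlating best with their own number. With the replicate number as a block, 85 rows were called for UC against NIBD, 209 for inflamed UC, 0 for non-inflamed UC (edgeR; 117 at an unadjusted p under 0.05) and 429 between the UC states, and let-7d-3p stood at 0.34 for non-inflamed UC. NIBD libraries bear only the numbers 1 to 16, so with the block the contrasts with NIBD rest mainly on UC libraries of those numbers. The fewer calls there cannot be told apart from this loss of samples.

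Of 23 list calls, 0 held in camera with an estimated correlation, and of the same 52 tests of a list in a comparison 30 passed in fry, 20 without the covariate and 23 with armless rows. fry asks whether a list moves on balance and compares it with no other miRNAs. The 37 shared calls fell to a median of 3.5 with the NIBD libraries split, with fewer samples per comparison. Of 146 called named values, 80 stayed past the threshold in every alternative on all index series, the replicate block included. Values under 10 are set to 0 in the table, which limits what low rows can show.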

Other observations

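Of the X-linked cluster that holds miR-424, 5 further rows rose in both UC states. They were picked after their values were seen, and the cluster was not tested as a set. Against NIBD, miR-503 rose by 1.70 ± 0.23 (SE) on the log2 scale in inflamed and by 1.09 ± 0.22 in non-inflamed UC, miR-542-5p by 0.95 ± 0.18 and 0.92 ± 0.18, miR-542-3p by 0.71 ± 0.16 and 0.79 ± 0.16, miR-450b-5p by 1.04 ± 0.18 and 0.79 ± 0.18, and miR-450a-1-5p by 1.83 ± 0.40 and 1.93 ± 0.40. All 5 passed edgeR's quasi-likelihood test in both, and the largest adjusted p was 0.00306. All 5 lay under the average log2 CPM of 5 used in the naming rule, from 1.16 for miR-450a-1-5p to 4.77 for miR-503. Values under 10 are set to 0, which limits what such low rows can show. Between the UC states, miR-503 rose by 0.61 ± 0.15 while miR-542-5p (0.03 ± 0.13), miR-542-3p (-0.08 ± 0.11), miR-450a-1-5p (-0.11 ± 0.25) and miR-450b-5p (0.25 ± 0.12) did not pass.

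Single miRNAs of the clusters related to miR-17, picked after their values were seen, went both ways between the UC states, while their list did not pass (camera adjusted p = 0.457). miR-17-5p and miR-20a-5p, of the cluster on chromosome 13, fell by 0.43 ± 0.09 and 0.51 ± 0.10 in inflamed tissue. miR-20b-5p and miR-363-3p, of the related X-linked cluster, rose by 0.59 ± 0.20 and 0.76 ± 0.22, while miR-106a-5p of that cluster did not pass (0.24 ± 0.15) and miR-19b-2-3p, whose reads are shared with the copy on chromosome 13, fell by 0.20 ± 0.08. miR-18a-5p, miR-19a-3p and miR-92a-1-3p of chromosome 13 did not pass.

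In the 3 patterns weighed next, the tests of a lower epithelial share, of blood and the epithelial fall, of blood and the myeloid rise in non-inflamed UC, of the index series and miR-31-5p, and all 4 counts of other splits were chosen after the results were seen. Splits that treat each library as an independent sample gave fewer calls than the real groups in each comparison. Samples of 1 patient may break that assumption, so chance is not fully excluded. For UC against NIBD, 1 of 100 splits of the samples within index series, the real one, gave as many calls (205; highest other 42). For inflamed UC against NIBD it was 1 of 100 (439; highest other 38), for non-inflamed UC against NIBD 1 of 100 (38; highest other 6) and for inflamed against non-inflamed UC 1 of 100 (437; highest other 89).

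In inflamed UC, most epithelial miRNAs were lower and most blood-cell miRNAs higher. A lower share of epithelial cells alone would raise all other lists alike, but the erythrocyte list rose more than the smooth muscle list by 1.12 (95% CI 0.65 to 1.59) on the log2 scale against non-inflamed UC. Blood left in the tissue would lower all tissue miRNAs alike, but the fibroblast list moved above the epithelial list by 1.28 (95% CI 0.87 to 1.70). These 2 contrasts, and that of the myeloid and erythrocyte lists in non-inflamed UC, were picked from list changes already seen. Their intervals give the size of the differences and are not independent tests. The myeloid list kept a rise of 0.41 (95% CI 0.13 to 0.69; 0.52 before) with the erythrocyte list as a covariate, and in non-inflamed UC it rose more than the erythrocyte list by 0.80 (95% CI 0.23 to 1.37). More blood may still account for the erythrocyte rise itself, and fewer epithelial cells together with more myeloid cells remain a hypothesis that cannot be separated here from changes within cells.

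miR-31-5p was higher in both UC states than in NIBD. Over 3 scalings of the libraries its lowest log2 fold change was 3.36, but TMM factors of 0.665 to 1.371 left no room for another outcome. Index series does not account for the direction, since the lowest value within a series for non-inflamed UC was 2.43 ± 0.92 (SE). In non-inflamed UC the miR-31-5p call was lost in index series 1, 2 and 3 alone, which hold fewer samples. A difference in colon segment might change miR-31-5p. The HOX cluster list was used as a covariate, as a stand-in for position. With it the log2 fold change was 3.30 ± 0.71 in inflamed UC (4.26 before, edgeR adjusted p = 0.0006). In non-inflamed UC it was 3.10 ± 0.64 (3.36 before, edgeR adjusted p = 0.000723). The HOX list itself fell in inflamed UC, so segment stays open as far as that list misses it.

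The second principal component followed the index series. Depth does not account for it: with all libraries thinned to 2.70 megacounts and values under 10 set to 0, the highest R squared of index series over 4 components was 0.75 (0.64 before). Nor does an unequal mix of groups, since it was 0.69 with the group means taken out. No biological explanation was tested, and differences in library preparation or in the patients of each series stay open.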
